A study of Homo sapiens with 4 samples.

How the data were processed

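RNA immunoprecipitation with sequencing (RIP-seq) of 3xFlag-tagged ALKBH5 was measured in NOMO-1 cells, in 2 input and 2 Flag-IP libraries with the replicate numbers 1 and 3. Per the labels' protocols, cells were infected with a lentivirus carrying the ALKBH5 coding sequence, selected with puromycin, sorted for GFP and crosslinked with UV light; RNA was fragmented, pulled down with an anti-Flag antibody, released with proteinase K and purified, and libraries were made with a TruSeq stranded mRNA kit and sequenced on an Illumina HiSeq instrument.

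Per the submitters' processing notes, reads were aligned with STAR to GRCh38 and quantified with RSEM; versions and the gene annotation are not given in the sources used here. The values the authors deposited are TPM per gene symbol, for 26830 symbols in 4 libraries, rounded to 2 decimals. Each library sums to 1000000 within rounding, which was taken as the unit TPM. TPM keeps no depth: the number of reads per library is unknown, so no count intervals or detection floors are given, and a value listed at 0 is not a measured absence. Gene types, coordinates and lengths were taken from GENCODE 29 by gene name. Of the symbols, 23819 matched directly and 24 through an older symbol, and 2987 did not match or were ambiguous.

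The comparison was Flag-IP against input with all 4 libraries. Genes with a mean of at least 1 TPM were tested on log2(TPM + 1), as deposited, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend and no robust option). Tests were two-sided with the Benjamini-Hochberg adjustment over all genes tested, at an adjusted p below 0.05. The prior degrees of freedom were infinite on the deposited scale and 4.02 on the median-ratio scale, with 2 residual degrees of freedom. The test, filter, threshold, alternatives, gene lists and naming rule were fixed before the data were examined, median-ratio scaling among them; giving its values beside the deposited ones was decided after seeing that most genes were higher on the deposited scale. In median-ratio scaling each library is divided by the median over tested genes of its ratio to the gene's geometric mean, over genes above 0 in all libraries. Structural RNAs are ribosomal, 7SL, 7SK, RNase P and MRP, Y, vault, spliceosomal, nucleolar, Cajal body and microRNAs and the MTRNR2L pseudogenes.

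Gene lists with at least 5 tested genes were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists, and with an estimated correlation beside it. That estimate rests on 2 residual degrees of freedom, so the test with it has little power. A list that does not pass it is not shown to be unchanged. Of 24 lists 22 were tested. They were m6A erasers and writers, m6A readers, cytosolic ribosomal proteins, histones, small nucleolar, Cajal body and spliceosomal RNAs, other abundant noncoding RNAs, SR and speckle factors, zinc finger proteins, chromatin regulators, the HOXA and KMT2A-rearranged programme, myeloid genes, mitosis, DNA replication, ribosome biogenesis, translation factors, oxidative phosphorylation, glycolysis, immediate early genes, interferon-stimulated genes, chaperones, apoptosis and p53 targets, and mRNA decay and export factors. Each list's members were also adjusted over the list alone. Named were ALKBH5, TACC3, the 12 genes per direction with the largest log2 difference among genes past the threshold with a mean of at least 5 TPM and no overlap between groups, pseudogenes and unnamed loci left out, and, per list, the 2 members with the highest mean and the 2 with the largest difference. Outside this rule, ASXL2 was named after its value was seen, FOXM1 and USP1 as the tested members of the list of reported targets, which was too small for a test, and NKG7 as the only marker of another cell type at 1 TPM or more. Mitochondrially encoded mRNAs were not analysed here.

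The test was checked on simulated data with 4163 genes, all with the same noise and no shift in structural RNA between groups. The check therefore does not cover the shift of most genes on the deposited scale. Of 50 genes set per size and direction only those past the filter were counted, 38 at 1 lower and 31 at 2 lower. On the deposited scale 92% of genes set 1 log2 unit higher and 68.4% of genes set 1 lower were recovered, 100% at 2 log2 units in either direction, and 0.35% of unchanged genes were called; on the median-ratio scale the shares were 84%, 73.7%, 100% and 0.13%. Alternatives were median-ratio and quantile scaling, no filter and a filter at a mean of 5 TPM, a pseudocount of 0.1, no mean-variance trend, the replicate number as a block, an adjusted p below 0.1, a fold of at least 2, an estimated correlation, and each library left out in turn. Chosen after seeing the data were rescaling without structural RNAs, a crossed replicate block, removal of the length trend (loess, span 0.5) and the median-ratio scale as a starting point. The length trend was fitted over all tested genes with a length, structural RNAs included. Rescaling without structural RNAs also took these RNAs out of the genes and lists tested. The interval of the median, the random lists and the permutations used the seed 20, and the intervals of rho a seed of their own. They were run with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.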

Results

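RNA bound to the m6A demethylase ALKBH5 was sequenced in NOMO-1, a human acute myeloid leukaemia cell line with monocytic features. ALKBH5 removes the methyl group from N6-methyladenosine (m6A), a common internal mark of mRNA. The cells carried a lentivirus for 3xFlag-tagged ALKBH5 and were crosslinked with UV light, and the tagged protein was pulled down with an anti-Flag antibody (RNA immunoprecipitation sequencing, RIP-seq). There were 4 libraries in 2 groups, 2 of input RNA taken before the pull-down and 2 of RNA recovered with the antibody, named input 1 and 3 and Flag-IP 1 and 3. Expression was given in TPM, relative transcript abundances that sum to 1000000 in every library, so the sequencing depth of a library is unknown and no counting error can be given. No pull-down from cells without the tag is analysed here, so the background of the immunoprecipitation was not measured. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

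The RNA classes in the Flag-IP libraries differed from those in input (mean ± SD of the share of TPM, n = 2 in each group throughout). The ribosomal RNAs of the large subunit, 28S and 5.8S together, made up 41.9% ± 2.88 of input and 22.6% ± 4.65 of Flag-IP. 18S RNA of the small subunit stood at 41.1% ± 2.10 and 44.5% ± 2.16. Both Flag-IP libraries lay above both inputs, though input 3 (42.6%) and Flag-IP 3 (43.0%) were close. 7SL, the RNA of the signal recognition particle, was at 8.99% ± 0.499 and 15.6% ± 1.33, and 7SK, the nuclear RNA that holds the elongation factor P-TEFb inactive, at 0.664% ± 0.0502 and 4.82% ± 0.417. Structural RNAs in all took 96.6% ± 0.322 of input and 93.0% ± 0.760 of Flag-IP. All other genes, mostly mRNAs, therefore shared 3.43% ± 0.322 of input and 6.95% ± 0.760 of Flag-IP, a ratio of 2.03. The inputs listed 4076 and 4543 genes at 1 TPM or more and the Flag-IP libraries 7970 and 7249. These shares were not tested.

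**Figure D1:**
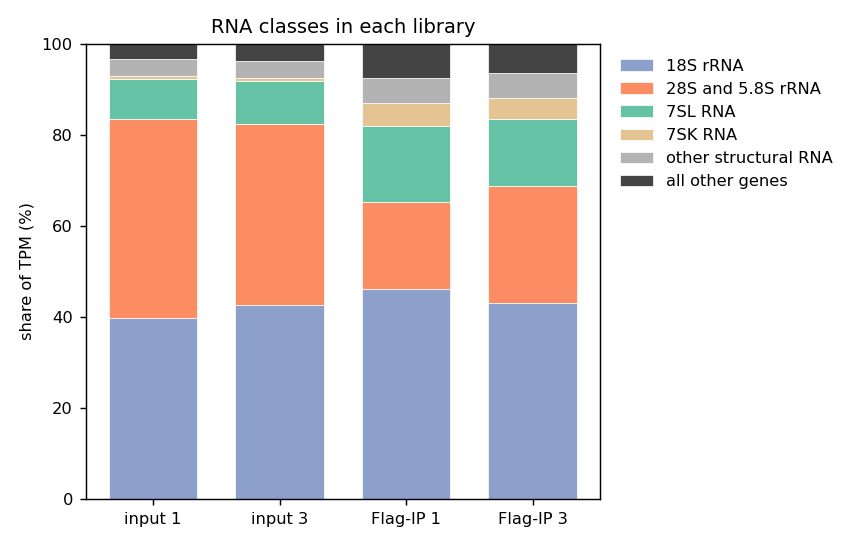
Share of TPM in percent (y axis) taken by classes of RNA in each of the 4 libraries (x axis), stacked to 100%. The 28S and 5.8S RNAs fall from 41.9% of TPM on average in input to 22.6% in Flag-IP, while 7SK and all other genes take larger shares in both Flag-IP libraries.

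Input and Flag-IP were compared to ask which transcripts are recovered with ALKBH5. Among genes with a mean of at least 5 TPM, pseudogenes left out, PKD1 increased most. This gene of the membrane protein polycystin-1 went from 0.425 ± 0.0495 TPM in input to 19.2 ± 0.608 TPM in Flag-IP, a ratio of 45.3. KMT2D and KMT2B, histone H3 methyltransferases, went from 1.80 ± 0.375 to 28.7 ± 4.39 TPM and from 0.840 ± 0.113 to 17.0 ± 1.09 TPM. MDN1, a giant ATPase of ribosome assembly, went from 0.670 ± 0.0424 to 14.8 ± 3.44 TPM, and OGT, the enzyme that adds O-linked N-acetylglucosamine to proteins, from 1.00 ± 0.262 to 17.0 ± 4.14 TPM.

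On the deposited scale most genes were higher in Flag-IP. Of 6487 genes with a mean of at least 1 TPM, limma on log2(TPM + 1) called 5616 higher and 48 lower at an adjusted p below 0.05, and 823 did not pass. The median gene was 0.84 higher on the log2 scale, and 2.38 times higher in mean TPM. Changes were therefore also taken relative to the typical gene, with the libraries scaled by the median ratio of the tested genes. On this median-ratio scale 1444 genes were higher and 1207 lower, so that higher calls fell from 99.2% to 54.5% of all calls. All 1444 were also higher on the deposited scale, 43 genes were lower on both, and 477 were higher on the deposited scale but lower on the median-ratio scale. At least 2-fold higher in each Flag-IP library than in either input were 1436 genes on the deposited scale and 211 on the median-ratio scale, and at least 2-fold lower 4 and 61. Both Flag-IP libraries lay above both inputs for 6039 genes and below for 71 on the deposited scale, and for 2399 and 2409 on the median-ratio scale, where chance alone gives 16.7% in each direction. A log2 difference on either scale understates the change of genes near 0 TPM, because 1 is added to each value. Without Flag-IP 1 the lower genes numbered 28 on the deposited scale, and the median-ratio counts were 961 higher and 587 lower; without Flag-IP 3, 2597 genes were at least 2-fold higher on the deposited scale. At least 2-fold lower were 8 to 20 genes when 1 library was left out. On the deposited scale limma found no spread between genes beyond its trend with level, so a gene's error there is that of the trend, a residual SD between 0.0954 and 0.215, and p-values there may be too small. HIST2H2BA, above 0 in a single library, had an adjusted p of 5.6e-42 in limma on that scale and 0.21 on the median-ratio scale.

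**Figure D2:**
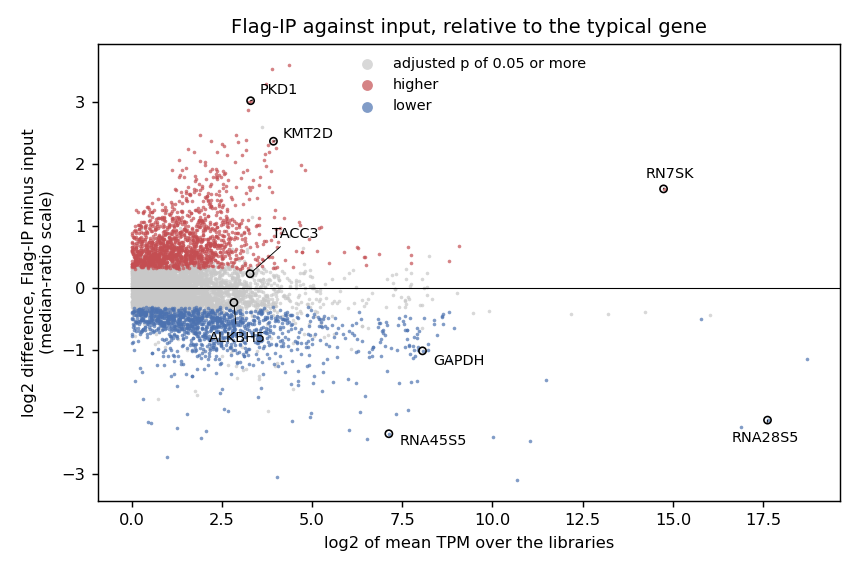
Log2 difference between Flag-IP and input on the median-ratio scale (y axis) against log2 of the mean TPM over the 4 libraries (x axis), 1 point per tested gene. Red points are the 1444 genes higher and blue points the 1207 lower at an adjusted p below 0.05 in limma; PKD1 and RN7SK (7SK) lie high above 0, and RNA28S5 (28S) and RNA45S5 far below, while ALKBH5 and TACC3 lie close to 0.

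The 12 genes with the largest increase among those with a mean of at least 5 TPM, pseudogenes left out, were higher in both Flag-IP libraries than in both inputs and passed limma on the deposited and the median-ratio scale. Relative to the typical gene PKD1 (chromosome 16, 2088710 to 2135898, minus strand, GRCh38) was higher by 3.02 ± 0.14 (log2 ± SE, adjusted p = 0.000386), KMT2B (chromosome 19, 35718019 to 35738878, plus strand) by 2.38 ± 0.11 and KMT2D (chromosome 12, 49018975 to 49059774, minus strand) by 2.36 ± 0.11. On the deposited scale, where the median gene was at 0.84, the same genes stood at 3.83, 3.29 and 3.40 (limma adjusted p = 4.7e-68, 1.9e-50 and 4.5e-53). 3 ubiquitin ligases of unusual size were among them: MYCBP2 reached 47.1 ± 11.2 TPM in Flag-IP against 4.44 ± 0.651 in input, HERC1 24.0 ± 4.57 against 1.73 ± 0.0778, and HERC2 23.4 ± 3.86 against 1.83 ± 0.141. LYST, a regulator of lysosomal trafficking, was at 26.1 ± 8.75 TPM against 1.82 ± 0.0354, and FRS3, an adaptor of fibroblast growth factor receptors, at 30.1 ± 2.46 against 2.10 ± 0.113. PILRB, an immunoglobulin-like receptor, and the readthrough gene STAG3L5P-PVRIG2P-PILRB that overlaps it were at 10.9 ± 1.64 and 11.3 ± 0.750 TPM in Flag-IP, against 0.405 ± 0.191 and 0.450 in input. Reads of these overlapping loci cannot be told apart, and PKD1 and HERC2 have near-identical pseudogene copies, so the levels of these 4 are uncertain. Relative to the typical gene, the 12 ranged from 1.98 (MYCBP2) to 3.02.

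**Figure D3:**
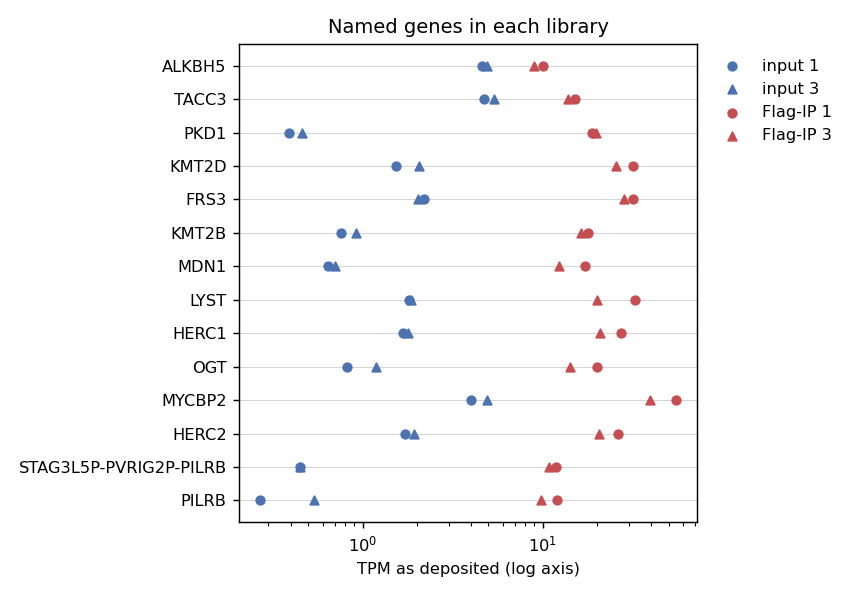
TPM as deposited (x axis, log scale) of ALKBH5, TACC3 and the 12 genes with the largest increase (y axis), 1 point per library, blue for input and red for Flag-IP. Every red point lies to the right of both blue points of its gene; the gap is narrow for ALKBH5 (ratio of means 1.99) and wide for PKD1 (45.3).

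The transcript of the tagged protein itself was not enriched relative to other genes. ALKBH5 (chromosome 17, 18183078 to 18209954, plus strand) was at 4.77 ± 0.205 TPM in input and 9.50 ± 0.834 TPM in Flag-IP, a ratio of 1.99, where the median gene had 2.38. Its log2 difference was 0.86 ± 0.21 on the deposited scale (limma adjusted p = 1.1e-04), and relative to the typical gene it was -0.24 ± 0.11 (adjusted p = 0.12); with quantile scaling it was -0.14, and with structural RNAs left out of the scaling -0.02. In input, 838 tested genes other than structural RNAs had a higher mean than ALKBH5. TACC3 (chromosome 4, 1721490 to 1745176, plus strand), a spindle protein whose mRNA has been reported as an ALKBH5 target in this leukaemia, was at 5.04 ± 0.431 and 14.4 ± 0.962 TPM, a ratio of 2.86. Its deposited difference was 1.35 ± 0.21 (limma adjusted p = 1.6e-09). Relative to the typical gene it was 0.23 ± 0.11 and did not pass (adjusted p = 0.13), while with quantile scaling it was 0.38 and passed (adjusted p = 0.033), as it did with structural RNAs left out (0.45, adjusted p = 0.0049). 35.2% of tested genes had a larger ratio than TACC3. As TACC3 may have been picked on these libraries, its direction is not independent evidence. Of the 11 transcripts listed as reported ALKBH5 targets, 4 could be tested, too few for a list test, and the other 3 were at -0.37 (FOXM1, adjusted p = 0.059), -0.13 (USP1, adjusted p = 0.48) and -0.18 (MYC, adjusted p = 0.20; 0.02 to 0.06 with quantile scaling, structural RNAs left out or a filter at 5 TPM) relative to the typical gene.

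Under the same rule, with pseudogenes left out, the 12 genes with the largest decrease were all structural RNAs of the ribosome, the nucleolus and the spliceosome. RNA5S9, a 5S ribosomal RNA, was at 2878 ± 746 TPM in input and 1345 ± 759 in Flag-IP, and RNA45S5, the ribosomal precursor, at 190 ± 11.5 and 89.995 ± 26.3. SNORA40, a small nucleolar RNA that guides pseudouridylation, was at 88.3 ± 12.01 and 41.9 ± 5.83, and RNU5B-1, a U5 RNA of the spliceosome, at 102 ± 11.3 and 60.0 ± 1.27. As deposited, the 12 genes named by rule lay between -1.20 (RNA5S9) and -0.66 (SNORA15), all past limma's threshold, and relative to the typical gene between -2.46 and -1.69. The others were RNA5-8S5, RNA28S5, SNORA22, SNORA37, SNORA63, RNU5A-1 and RNU5F-1. For some of them input 3 and Flag-IP 3 lay close, such as SNORA15 (5.47 and 5.25 TPM), SNORA37 (7.31 and 5.93) and RNU5A-1 (219.95 and 193.76). With quantile scaling the difference of RNA28S5 was 0.00, since it held the same rank in all libraries, and RNA5S9 (-1.24, adjusted p = 0.21) and RNA5-8S5 (-0.65, adjusted p = 0.23) no longer passed. Without a filter the median-ratio calls of RNA28S5, RNA5S9, RNA5-8S5, SNORA15 and SNORA37 were lost (adjusted p = 0.0566, 0.0614, 0.0913, 0.0565 and 0.0503). So were those of RNA5-8S5 without input 1 (-1.79, adjusted p = 0.053) and SNORA15 with the length trend removed (-1.06, adjusted p = 0.051). Of 206 structural RNAs tested, 43 were lower on the deposited scale and 94 higher, against 4 lower and 5400 higher of 6136 protein-coding genes; on the median-ratio scale 79 structural RNAs were lower and 10 higher, against 1105 and 1372 protein-coding genes. Many of these RNAs have near-identical copies, so the value of a single copy is uncertain.

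Large chromatin regulators were among the gene lists fixed beforehand. Of 35 tested, 27 were higher relative to the typical gene and 1 (ASXL2, named after its value was seen) lower, with a median log2 difference of 0.86. Besides KMT2D and KMT2B, CHD4, a nucleosome remodeller, was at 8.25 ± 1.13 TPM in input and 22.7 ± 3.16 in Flag-IP (0.18, not passed). CHD4 passed with quantile scaling (0.44, adjusted p = 0.027), structural RNAs left out (0.41, adjusted p = 0.0067) or a filter at 5 TPM (0.38, adjusted p = 0.021), and turned to -0.07 with the length trend removed (adjusted p = 0.59). All 35 were higher on the deposited scale, with a median of 1.74. limma's camera called the list on both scales (adjusted p = 9.3e-11 and 1.5e-16), but not with an estimated correlation between genes (adjusted p = 0.71 and 0.997). Adjusted over the list alone, 27 were higher and 1 lower. Across 5974 protein-coding genes the median-ratio difference rose with the length of the longest annotated transcript (Spearman's rho 0.47). Genes are not independent replicates. This list's median length was 9363 bases. With the length trend removed the list's median was 0.39 above that of all genes (adjusted p = 7.2e-05).

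Some splicing and RNA decay factors were higher. Of 31 SR proteins and nuclear speckle factors, 15 were higher and 1 lower relative to the typical gene (16 and 2 adjusted over the list alone), with a median of 0.39. CLK1, a kinase of SR proteins, went from 0.790 ± 0.325 to 10.4 ± 2.93 TPM (1.79 ± 0.16), and SF3B1, a core factor of branch point recognition, from 12.6 ± 1.29 to 61.2 ± 15.0 TPM (0.96 ± 0.11). SRRM2, which builds the speckle, was at 0.13 and did not pass. It passed with quantile scaling (0.41, adjusted p = 0.027), structural RNAs left out (0.36, adjusted p = 0.011) or a filter at 5 TPM (0.34, adjusted p = 0.026), and turned to -0.25 with the length trend removed (adjusted p = 0.11). Of 31 mRNA decay and nuclear export factors, 12 were higher and 2 lower (14 and 2 adjusted over the list alone), with a median of 0.25. SMG1, the kinase of nonsense-mediated decay, went from 0.965 ± 0.0636 to 15.8 ± 3.61 TPM (2.15 ± 0.11) and has near-identical pseudogenes. DDX39B, an export helicase, went from 4.33 ± 0.580 to 27.0 ± 5.37 TPM (1.25 ± 0.10), while DDX39A was at -0.28 (0.03 with the length trend removed) and did not pass. camera called the SR list on the median-ratio and deposited scales (adjusted p = 0.0036 and 0.0019) and the decay list likewise (adjusted p = 0.023 and 0.030). With an estimated correlation neither passed (adjusted p = 0.71 and 0.74 on the median-ratio scale, 0.997 on the deposited scale). On the median-ratio scale the decay list lost its call with quantile scaling (0.23, adjusted p = 0.057), with the length trend removed (0.07, adjusted p = 0.18), without a filter (0.13, adjusted p = 0.10), without input 3 (0.30, adjusted p = 0.075) and without Flag-IP 1 (0.19, adjusted p = 0.065). Its deposited call was lost with quantile scaling, with the length trend removed (0.14, adjusted p = 0.10), without input 3 (0.15, adjusted p = 0.077) and without Flag-IP 1 (0.15, adjusted p = 0.20). The SR list lost its call only on the deposited scale, with a filter at 5 TPM (adjusted p = 0.090) and without Flag-IP 1 (0.44 above the median of all genes, adjusted p = 0.050).

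Translation factors, myeloid genes and small noncoding RNAs lay below the typical gene. Of 34 translation initiation and elongation factors, 20 were lower and 3 higher (22 and 3 adjusted over the list alone), with a median of -0.42. As deposited, 21 were higher and 0 lower, over the list alone too. EEF2, the translocation factor, was at 220 ± 31.3 TPM in input and 245 ± 11.1 in Flag-IP (-1.10 ± 0.12), and EEF1A1, which delivers aminoacyl-tRNA, at 182 ± 15.4 and 229 ± 20.1 (-0.93 ± 0.11). EIF4G3 went the other way (0.66 ± 0.11). Of 18 monocytic and myeloid genes, 8 were lower and none higher (11 and 0 adjusted over the list alone), with a median of -0.40. As deposited, 13 were higher and 0 lower, over the list alone too. CTSG and ELANE, proteases of granules, went from 29.4 ± 1.45 to 49.3 ± 3.99 TPM and from 13.6 ± 2.91 to 22.4 ± 0.530 TPM, that is -0.51 and -0.50 relative to the typical gene; with quantile scaling CTSG was at 0.01 and ELANE at -0.22 (adjusted p = 0.26). Both calls were lost with the length trend removed (-0.13 each, adjusted p = 0.39 and 0.51) and without input 1 (adjusted p = 0.085 and 0.054), input 3 (0.054 and 0.17) or Flag-IP 1 (0.054 and 0.15). ELANE did not pass with structural RNAs left out (-0.27, adjusted p = 0.088), without a filter (adjusted p = 0.092) or with a filter at 5 TPM (-0.30, adjusted p = 0.14). Of 161 small nucleolar, Cajal body and spliceosomal RNAs, 58 were lower and 8 higher (the same numbers adjusted over the list alone), with a median of -0.77. Deposited values gave 70 higher and 30 lower (67 and 28 adjusted over the list alone). SNORD116-22, a small nucleolar RNA from an imprinted locus, went from 0.190 ± 0.269 to 8.98 ± 3.11 TPM (2.37 ± 0.25). SNORD116-4 was listed at 0 in both inputs and at a mean of 7.51 ± 3.78 TPM in Flag-IP. camera placed these lists lower on the median-ratio scale (adjusted p = 1.2e-05, 0.0011 and 1.4e-06) and, below the typical gene though not below input, on the deposited scale (adjusted p = 0.047, 0.030 and 9.6e-19). With an estimated correlation none passed (adjusted p = 0.70, 0.71 and 0.77 on the median-ratio scale, 0.997 on the deposited scale). With the length trend removed the median-ratio calls of the myeloid genes (-0.20, adjusted p = 0.13) and the small RNAs (-0.17, adjusted p = 0.24) were lost. The small RNAs themselves entered that trend as its shortest transcripts, so their lost call cannot separate length from the class of RNA. The translation factor call was lost with quantile scaling (-0.23, adjusted p = 0.073). The deposited call of the myeloid genes was lost without input 3 (adjusted p = 0.079), with the length trend removed (-0.12, adjusted p = 0.19), without a filter (0.05, adjusted p = 0.74) and with a filter at 5 TPM (adjusted p = 0.21), which also ended it on the median-ratio scale (-0.31, adjusted p = 0.051). The deposited call of the translation factors was lost without input 1 (adjusted p = 0.055) or input 3 (adjusted p = 0.23), with quantile scaling, without a mean-variance trend (adjusted p = 0.105), without a filter (0.22, adjusted p = 0.61) and with a filter at 5 TPM (adjusted p = 0.090).

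Ribosomal proteins, histones and metabolic genes were below the typical gene on the median-ratio scale, but not on every scaling. Of 77 cytosolic ribosomal proteins 46 were lower and 10 higher (48 and 11 adjusted over the list alone), with a median of -0.51, which became 0.03 above the median of all genes with quantile scaling. RPLP1 was at 389 ± 37.5 TPM in input and 598 ± 59.8 in Flag-IP (-0.64 ± 0.11), whereas RPS27 went from 221 ± 5.22 to 858 ± 129 TPM (0.68 ± 0.13). Of 56 replication-dependent histones 16 were lower and 4 higher, over the list alone too, with a median of -0.22, which turned to 0.34 above the median of all genes with quantile scaling. HIST1H2AI went from 255 ± 10.97 to 408 ± 12.5 TPM (-0.59 ± 0.15) and HIST1H3J from 12.8 ± 0.361 to 62.6 ± 5.61 TPM (0.99 ± 0.17). HIST2H2BA, at 48.9 TPM in Flag-IP 3 and listed at 0 in the other 3 libraries, rests on that library (adjusted p = 0.21, and 0.0018 without Flag-IP 1). The call of HIST1H2AI was lost with quantile scaling (-0.05, adjusted p = 0.73), the length trend removed (-0.12, adjusted p = 0.56), no filter (adjusted p = 0.075), a filter at 5 TPM (-0.37, adjusted p = 0.071) or the replicate number as a block (adjusted p = 0.067). It was also lost without input 1 (adjusted p = 0.13), input 3 (0.084) or Flag-IP 1 (0.066). That of RPLP1 was lost with the length trend removed (-0.29, adjusted p = 0.088) and without input 1 (adjusted p = 0.056) or input 3 (0.059), and that of RPS27 without input 3 (0.55, adjusted p = 0.090). Of 66 nuclear-encoded oxidative phosphorylation genes 20 were lower and 1 higher (15 and 0 adjusted over the list alone; median -0.18), and NDUFB9 was at -0.45 ± 0.10 and ATP5B at 0.06. NDUFB9 turned to 0.08 with quantile scaling (adjusted p = 0.60), and its call was lost with structural RNAs left out (-0.21, adjusted p = 0.084), the length trend removed (-0.165, adjusted p = 0.26) or a filter at 5 TPM (-0.235, adjusted p = 0.070). It was also lost without input 1 (adjusted p = 0.080), input 3 (0.10) or Flag-IP 1 (0.059). ATP5B passed with quantile scaling (0.55, adjusted p = 0.014), structural RNAs left out (0.30, adjusted p = 0.022) or a filter at 5 TPM (0.27, adjusted p = 0.049). Of 17 glycolytic genes 9 were lower and 0 higher (9 and 1 adjusted over the list alone; median -0.36), and GAPDH was at 245 ± 26.5 and 289 ± 13.1 TPM (-1.01 ± 0.12). Of 25 heat shock, chaperone and unfolded protein response genes 7 were lower and 1 higher, over the list alone too (median -0.23), with HSP90AB1 at -0.73 ± 0.10 (-0.19 with quantile scaling, adjusted p = 0.20). The deposited scale had 62 ribosomal proteins, 50 histones, 56 oxidative phosphorylation, 14 glycolytic and 23 chaperone genes higher and 0 lower (62, 51, 56, 14 and 24 higher adjusted over the list alone). camera called the 5 lists lower on the median-ratio scale (adjusted p = 7.3e-07, 0.0089, 0.011, 0.015 and 0.023, in this order) and none on the deposited scale. None passed with an estimated correlation (adjusted p = 0.71, 0.88, 0.71, 0.71 and 0.71). Quantile scaling ended all 5 of these calls, turned the glycolysis median to 0.07 (adjusted p = 0.80), and left the histones called higher (adjusted p = 0.0043). The histone call was also lost without Flag-IP 1 (-0.12, adjusted p = 0.155), and the chaperone call with structural RNAs left out of the scaling (-0.18, adjusted p = 0.062) and without input 3 (-0.20, adjusted p = 0.074) or Flag-IP 3 (-0.16, adjusted p = 0.087). With the length trend removed, oxidative phosphorylation turned to 0.07 (adjusted p = 0.79) and the histones to 0.21 (adjusted p = 0.22), and the chaperone call ended (-0.19, adjusted p = 0.091). At the length of the short histone mRNAs that trend was fitted partly to small RNAs. The filter at 5 TPM ended the calls of oxidative phosphorylation (-0.01, adjusted p = 0.56), glycolysis (-0.14, adjusted p = 0.22), histones (0.04, adjusted p = 0.84) and chaperones (-0.03, adjusted p = 0.56). Among deposited values the ribosomal proteins were called lower without Flag-IP 1 (adjusted p = 0.0046) or Flag-IP 3 (adjusted p = 0.0064), and the histones without Flag-IP 3 (adjusted p = 0.033), though their median stayed 0.15 above that of all genes. With the length trend removed camera called the histones higher (0.44, adjusted p = 6.3e-05). Without a filter it called histones (0.60, adjusted p = 2.5e-04), ribosomal proteins (0.32, adjusted p = 0.0035) and oxidative phosphorylation (0.47, adjusted p = 0.0017) higher. Those calls were made against a background with many genes near 0 TPM, so they say little about the lists.

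**Figure D4:**
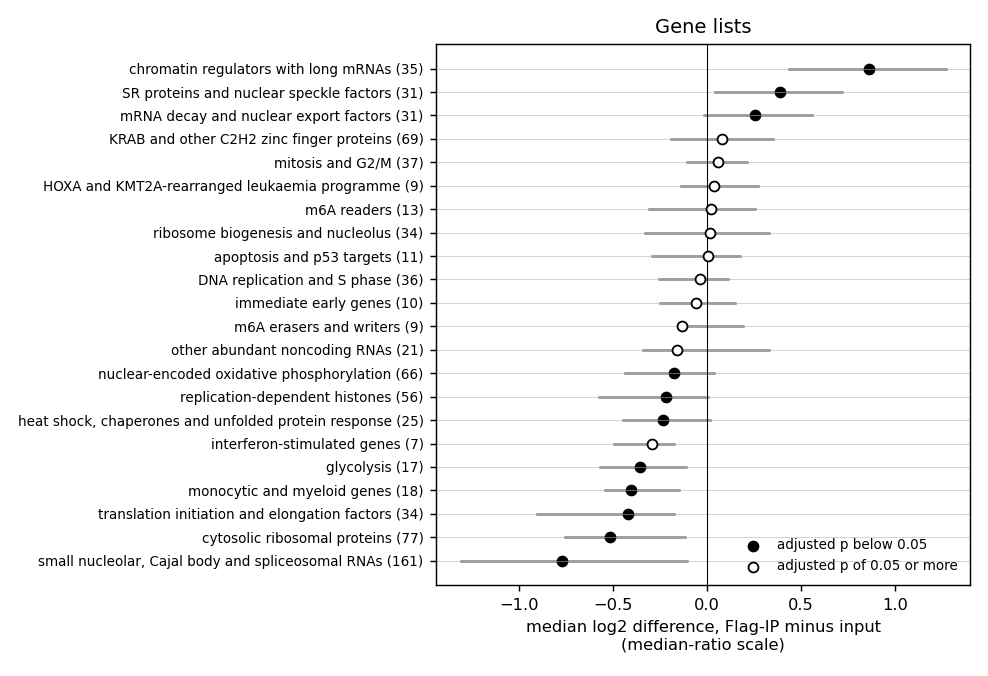
Median log2 difference between Flag-IP and input over the tested members of each gene list on the median-ratio scale (x axis), lists on the y axis with their number of members; grey lines span the middle 50% of members. Filled points are the 11 lists called by camera with its preset correlation, from chromatin regulators (0.86) to small nucleolar, Cajal body and spliceosomal RNAs (-0.77). With quantile scaling the ribosomal protein, histone and glycolysis medians turn positive. No list is called with an estimated correlation, a test with little power at 2 residual degrees of freedom.

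The remaining lists were not called on the median-ratio scale. On the deposited scale without a filter, mitosis (0.61), ribosome biogenesis (0.55) and DNA replication (0.48) were called higher (camera adjusted p = 0.0017 each). Without a filter the background holds many genes near 0 TPM, whose log2(TPM + 1) can hardly differ. Lists of expressed genes then lie above it when most expressed genes are higher, so these calls say little about the lists. RN7SK, the 7SK RNA, stood out among 21 other abundant noncoding RNAs, with 6635 ± 502 TPM in input and 48172 ± 4165 in Flag-IP (1.60 ± 0.14), as did SNHG15 (0.955 ± 0.0636 and 9.80 ± 0.445 TPM, 1.56 ± 0.11). In that list 6 were higher and 2 lower (the same adjusted over the list alone). On the median-ratio scale the list was not called (camera adjusted p = 0.89), with a median of -0.16 and a mean of 0.15. The median turned to 0.35 above that of all genes with quantile scaling, and to 0.27 with structural RNAs left out. Leaving them out also drops structural members such as RN7SK from the list, so this is not an effect of scaling alone. On the deposited scale the list was called higher (camera adjusted p = 0.0020, and 0.997 with an estimated correlation). That call was lost without Flag-IP 1 (adjusted p = 0.40) or Flag-IP 3 (adjusted p = 0.56), with the filter at 5 TPM (adjusted p = 0.090), with quantile scaling (adjusted p = 0.090) and with structural RNAs left out of the scaling (adjusted p = 0.20). Of 9 m6A erasers and writers 2 were higher and 2 lower, over the list alone too, with a median of -0.13 (adjusted p = 0.85). METTL3, the catalytic m6A methyltransferase, went from 0.675 ± 0.120 to 4.39 ± 0.332 TPM (0.90 ± 0.13), and METTL5, a ribosomal RNA methyltransferase, was at -0.52 ± 0.12. The METTL5 call was lost with structural RNAs left out (-0.31, adjusted p = 0.066), the length trend removed (-0.20, adjusted p = 0.26) or a filter at 5 TPM (-0.33, adjusted p = 0.090). It was also lost without input 1 (adjusted p = 0.082) or Flag-IP 3 (0.087). Of 13 m6A readers 3 were higher and 2 lower (3 and 4 adjusted over the list alone), with a median of 0.02 (adjusted p = 0.98), and PRRC2A was at 0.79 ± 0.11. Medians were 0.08 for 69 zinc finger proteins (17 higher, 9 lower; adjusted p = 0.46), 0.06 for 37 mitosis genes (5 higher, 2 lower; adjusted p = 0.85) and 0.04 for 9 genes of the HOXA and KMT2A-rearranged leukaemia programme (2 higher, 0 lower; adjusted p = 0.85). They were 0.02 for 34 ribosome biogenesis genes (7 higher, 5 lower; adjusted p = 0.998), 0.01 for 11 apoptosis and p53 targets (2 higher, 1 lower; adjusted p = 0.89; -0.07 with quantile scaling and -0.0160 with structural RNAs left out) and -0.04 for 36 DNA replication genes (5 higher, 6 lower; adjusted p = 0.71; 0.03 with quantile scaling). They were -0.06 for 10 immediate early genes (1 higher, 2 lower; adjusted p = 0.85) and -0.29 for 7 interferon-stimulated genes (1 higher, 1 lower; adjusted p = 0.24). Adjusted over the list alone, these 8 lists had, in the order given, 16, 2, 2, 7, 2, 3, 1 and 1 higher and 9, 1, 0, 5, 1, 2, 2 and 3 lower members. In the readers, the apoptosis list and the other abundant noncoding RNAs the median and the direction of the test differed in sign on the median-ratio scale. For deposited values they did so in the erasers and writers, oxidative phosphorylation, DNA replication, glycolysis and chaperone lists, whose medians lay above that of all genes while the test pointed lower. Single members moved in both directions, such as MEIS1 (0.52 ± 0.11) of the leukaemia programme, and MKI67 (-0.90 ± 0.10) and BUB1B (0.59 ± 0.11) of the mitosis list. Without Flag-IP 1 MEIS1 (0.42, adjusted p = 0.075) and BUB1B (0.50, adjusted p = 0.057) did not pass, nor did MEIS1 with the length trend removed (0.34, adjusted p = 0.0565). With the length trend removed the medians of the readers (-0.04), the zinc finger proteins (-0.05) and the other abundant noncoding RNAs (0.25) against that of all genes had the other sign, none past the threshold. The 13 mitochondrially encoded mRNAs were not analysed here.

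Markers of other cell types were checked for foreign RNA. Of 36 erythroid, lymphoid, megakaryocytic, fibroblast, epithelial and embryonic kidney markers in the table, 35 were under 1 TPM in every library, with a maximum of 0.31 TPM. NKG7, a granule gene of lymphocytes, was at 12.02 and 14.6 TPM in the inputs and 21.98 and 23.9 TPM in Flag-IP.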

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

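The main dependence is on scaling, because TPM are shares of a fixed sum. Chosen after seeing the data were rescaling without structural RNAs, the crossed block, the length trend and the median-ratio scale as a starting point. Median-ratio scaling gave 1444 genes higher and 1207 lower, 211 and 61 at least 2-fold, ALKBH5 at -0.24, TACC3 at 0.23 (adjusted p = 0.134 in limma) and 11 lists. Quantile scaling gave 1243 and 1219, 185 and 36 at least 2-fold, and ALKBH5 at -0.14. Rescaling without structural RNAs gave 2235 and 724, 317 and 8 at least 2-fold, and ALKBH5 at -0.0236. By construction median-ratio scaling and rescaling change all genes of a library by a single factor, and quantile scaling changes them by rank; which one is nearest to the RNA amounts was not tested.

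Values turned where their sign changed, past the threshold or not; for most of them neither sign passed. Also counted are 3 lists whose test changed direction with a call while the median kept its sign. Lists are given against the median of all genes. From the deposited scale, median-ratio scaling turned erasers and writers (-0.12), histones (-0.21), other noncoding RNAs (-0.15), zinc fingers (0.0914), DNA replication (-0.0272), oxidative phosphorylation (-0.17), glycolysis (-0.35), chaperones (-0.22) and apoptosis (0.0186). Quantile scaling turned erasers and writers (-0.0456), ribosomal proteins (0.0294), zinc fingers (0.0429), oxidative phosphorylation (-0.0258) and chaperones (-0.0280). Rescaling without structural RNAs turned erasers and writers (-0.0797), histones (-0.15), zinc fingers (0.0805), DNA replication (-0.0218), oxidative phosphorylation (-0.13), glycolysis (-0.28) and chaperones (-0.18). Removal of the length trend turned erasers and writers (-0.0768), readers (-0.000164) and ribosomal proteins (0.0539). No filter turned ribosomal proteins (0.32), myeloid genes (0.0518), translation factors (0.22), immediate early genes (0.0475) and apoptosis (0.0939), and for DNA replication (0.48) and oxidative phosphorylation (0.47) only the test, from lower to higher. The filter at 5 TPM turned other noncoding RNAs (-0.000837), ribosome biogenesis (-0.0883), glycolysis (-0.0692) and chaperones (-0.0249). A pseudocount of 0.1 turned erasers and writers (-0.0907), histones (-0.17), other noncoding RNAs (-0.16), zinc fingers (0.12), DNA replication (-0.0130), oxidative phosphorylation (-0.15), glycolysis (-0.30) and chaperones (-0.20).

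Starting from the median-ratio scale, quantile scaling left 5 lists called, removal of the length trend 5 and the filter at 5 TPM 6. On it, quantile scaling turned ribosomal proteins (0.0294), histones (0.34), other noncoding RNAs (0.35), DNA replication (0.0264), glycolysis (0.0696), apoptosis (-0.0706), HIST1H4K (0.45), SNORA109 (0.23), RN7SL1 (0.50), RN7SL2 (0.15), CTSG (0.00775), LGALS3 (0.0111), MCM7 (0.19), NDUFB9 (0.0790), ENO1 (0.18), MYC (0.0595) and HSPD1 (0.39). Rescaling without structural RNAs turned other noncoding RNAs (0.27, with the structural members dropped), apoptosis (-0.0160), ZC3H13 (0.0811), HIST1H4K (0.17), LGALS3 (0.10), IRF8 (0.0555), MCM7 (0.10), MYC (0.0423), HSPD1 (0.16) and GADD45B (0.14). Removal of the length trend turned readers (-0.0400), histones (0.21), other noncoding RNAs (0.25), zinc fingers (-0.0532), oxidative phosphorylation (0.0653), HNRNPA2B1 (-0.0404), HIST1H4K (0.45), SNORD3A (0.0315), RN7SL1 (0.0993), RN7SL2 (0.0263), SRRM2 (-0.25), ZNF207 (-0.25), CHD4 (-0.0743), ZEB2 (-0.36), LGALS3 (0.25), PGK1 (-0.11), HSPD1 (0.00998), GADD45B (0.26) and DDX39A (0.0260). No filter turned readers (-0.0587), zinc fingers (-0.00222), HOXA programme (-0.000891), ribosome biogenesis (-0.0160), apoptosis (-0.0129), HNRNPA2B1 (-0.0157), ZEB2 (-0.00392) and BCL2A1 (-0.0312). The filter at 5 TPM turned histones (0.0450), other noncoding RNAs (0.0547), DNA replication (0.11), ribosome biogenesis (-0.0959), ZC3H13 (0.0578), HIST1H4K (0.14), LGALS3 (0.0805), MCM7 (0.0792), MYC (0.0176), HSPD1 (0.14) and GADD45B (0.12). The cause was not tested.

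Without a filter 11 lists were called on the deposited scale. Genes near 0 TPM then enter the background and can hardly differ, so lists of expressed genes are raised against it there. Removing the length trend left 25 genes lower and 1 at least 2-fold lower. With a filter at 5 TPM fewer genes are tested: 1272 higher, 25 lower, 441 at least 2-fold higher and 3 lists on the deposited scale, and 392, 355 and 6 lists on the median-ratio scale. A pseudocount of 0.1 gave 2757 and 7 genes at least 2-fold higher and lower, since low values are damped less. With a fold of at least 2 as well, 2358 were higher and 17 lower. With an estimated correlation 0 lists were called, in a test with little power at 2 residual degrees of freedom.

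With 1 library left out, the lone library of a group is assumed to vary like the other group. Lower genes ranged from 28 to 57, genes at least 2-fold higher from 1504 to 2597 and lower from 8 to 20, and called lists from 4 to 8. Ranges over the left-out libraries that include a turned value were, on the deposited scale, readers (-0.0366 to 0.0825), glycolysis (-0.0531 to 0.0267), chaperones (-0.11 to 0.0741) and erasers and writers (-0.0230 to 0.0506). On the median-ratio scale they were readers (-0.0386 to 0.0856), HNRNPA2B1 (-0.0426 to 0.10), LGALS3 (-0.36 to 0.13), immediate early genes (-0.20 to 0.0164), HIST1H4K (-0.17 to 0.0158), GADD45B (-0.19 to 0.0794), HOXA programme (-0.0444 to 0.12), ZEB2 (-0.0508 to 0.12), apoptosis (-0.12 to 0.0225) and HSPD1 (-0.17 to 0.0297). The histones ranged from 0.15 to 0.21 on the deposited scale, where the test pointed lower without Flag-IP 3 with the median above 0. On the median-ratio scale 961 to 1135 genes were higher and 587 to 837 lower. The cause was not tested.

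Same-numbered libraries did not deviate together (correlation of deviations -0.17, and -0.19 on the median-ratio scale). With 2 libraries per group this is a single contrast, and the labels do not say whether a number marks a shared lysate. Pairing therefore stays open. With the replicate number as a block 4789 genes were higher and 35 lower, and 1286 and 1055 on the median-ratio scale, of which 1268 and 1022 were shared with the fit without the block; 7 and 11 lists were called. With crossed numbers as a block the counts were 5908 and 58, and 1409 and 1275, with 5 and 11 lists called; on the deposited scale the myeloid (adjusted p = 0.0937), translation factor (0.230) and decay (0.0937) calls ended and the histones were called higher (0.0223).

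All other counts stayed within 1.5 times, such as 5810 higher and 49 lower at an adjusted p below 0.1. On the deposited scale 477 genes that were lower on the median-ratio scale were called higher; in the alternatives that start from the median-ratio scale 0 called genes were called in the opposite direction. Of the values of named genes under alternatives, 1078 kept direction and side of the threshold, 38 gained a call, 113 lost it and 52 turned; of those of lists 448, 10, 40 and 80. What depth limits is unknown.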

Other observations

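Pseudogenes were frequent among the largest increases on the deposited scale, 13 of the top 50 against 83 of all tested genes (1.28%). The filter takes the mean over all libraries, so rows low in input pass only where Flag-IP is high. Low-level rows are thereby selected for an increase, and how far this holds for the pseudogenes was not tested. The following genes were chosen after their values were seen. Relative to the typical gene, SMG1P1 and SMG1P3, copies of the decay kinase SMG1, stood at 3.60 and 3.28. HERC2P9 and HERC2P3, copies of the ubiquitin ligase HERC2, stood at 3.00 and 2.86, and SDHAP1, a copy of a succinate dehydrogenase subunit, at 2.15. MTRNR2L2, a pseudogene related to mitochondrial 16S ribosomal RNA, fell from 2590 ± 741 to 721 ± 164 TPM (mean ± SD, n = 2).

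The test of the structural RNA share was chosen after its result was seen. No pattern below was set against a biological group of samples, so no biological explanation was tested.

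Most genes were higher on the deposited scale, with a median of 0.85 for genes other than structural RNAs. A smaller share of structural RNA in a fixed sum would raise all others. After rescaling without structural RNAs the median was 0.16 (95% bootstrap interval 0.148 to 0.174), but this rescaling fixes the total of the remaining genes, so a median near 0 is largely set by the centring. The test therefore decides nothing about how much of the shift the share could explain, and the cause stays open.

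Long transcripts lay higher than short ones. Across 5974 protein-coding genes rho with transcript length was 0.469 on the median-ratio scale (interval 0.448 to 0.490). On the deposited scale rho was 0.381, and 0.322 to 0.401 in single pairs of libraries. With genes in 5 groups by length, the median rose from the shortest to the longest, from -0.30 to 0.30. With length and level held fixed, genomic span kept a partial rho of 0.131, which would be consistent with some unspliced RNA, while transcript GC had 0.0334 and length given GC and level 0.446, so GC does not explain the trend. The chromatin regulators lay at percentile 99.71 of random lists matched on length and level, and the SR list at 99.95. At the low end were the translation factors (0.09) and the cytosolic ribosomal proteins (0.57). The decay list (93.43), the myeloid genes (6.875), oxidative phosphorylation (92.81) and the histones (96.995) were less extreme. Random lists draw genes singly, while list members may vary together, so these percentiles may be too extreme. The estimated correlation of the chromatin regulators was 0.919 on the deposited scale, where shifts of whole libraries also enter. The percentiles were taken on the median-ratio scale. Length alone may not account for the chromatin regulators. Whether long RNA is bound by ALKBH5 or recovered by the pull-down without it cannot be separated without cells lacking the tag.

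Pseudogenes moved with their parents on the median-ratio scale. Over 34 pairs with 25 distinct parents rho was 0.799, and 0.765 with 1 value per parent (permuted pairs -0.329 to 0.344). This is consistent with reads shared between copies. The pseudogene median was 0.85 against 0.22 for the parents, and 26 of 34 lay above their parent, so sharing in proportion to the parent would not give the whole difference. The filter on the mean also keeps rows low in input only where Flag-IP is high, which may add to this difference.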
